A study of Mus musculus with 9 samples.

How the data were processed

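The material was RNA of sorted pre-B cells from Eµ-Myc mice of 3 genotypes, in 9 libraries, 3 per group. Per the labels' protocols, total RNA was extracted from sorted cells and made into stranded libraries with poly(A) selection, which were read from a single end. The deposited values are whole-number read counts per Ensembl gene, not normalised, with a separate file for each library and no pooling of replicates. The submitters' processing notes name bcl2fastq 2.17.1.14, STAR 2.5.3a and DESeq2 and the mouse build mm10, also called GRCm38. The counting tool, its strand setting and the annotation release are not given in the sources used here. Counts of overlapping or antisense genes, and of families with near-identical members such as the Ifi200 genes, ribosomal protein genes, globins and MHC genes, are therefore uncertain to the extent that the counting could share reads between them. Groups and replicate numbers were taken from the labels. The labels give no litter, day or sequencing batch.

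Gene names, positions, GC content and transcript lengths came from GENCODE release M21 on GRCm38, to which 49326 gene identifiers of the files matched. The other 259 held 0.0163% of all counts and kept their identifier as name. Total counts per library ran from 23266867 to 37697481. A gene with 0 counts in a group was treated as having at most 3 counts over the group, and a ratio against 1 to 3 counts is given with its exact 95% interval. Such intervals and bounds cover counting error only, since reads without molecular identifiers are not independent molecules.

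Counts were tested with edgeR 4.0.16 under R 4.3.3. The steps were the default filter on low counts given the groups, TMM scaling factors (0.977 to 1.03), a model with a mean for each genotype, robust quasi-likelihood dispersions and the quasi-likelihood F test. All 9 libraries entered a single fit, which left 6 residual degrees of freedom, and the common dispersion was 0.0150. The 3 pairwise comparisons and a joint test of any difference between genotypes were made. P-values were adjusted by the Benjamini-Hochberg method over the 13122 genes tested, with a threshold of 0.05, and every adjusted p of a gene is two-sided and from this fit unless another tool is named. Fold changes are on the log2 scale as edgeR fits them, and their standard errors (SE) come from the same fit. CPM were computed with the TMM factors and are given as mean ± SD of 3 libraries.

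A set of 37 gene lists was written down before the data were examined. It covers pathways, stages of the B lineage, other cells that a sort could hold, quality and the neighbours of both targeted genes. Lists with at least 5 measured members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), two-sided, with the preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. camera with a correlation estimated from the data and fry were run as alternatives. With the estimated correlation 0 lists passed in any pairwise comparison (3, 2 and 4 lists at an unadjusted p under 0.05), while fry called 18, 1 and 14 lists in Parp1_KO against WT, Parp2_KO against WT and Parp1_KO against Parp2_KO. Counts of members past the threshold over all genes tested are given first, and those adjusted over the list alone are named as such. A median with genes at 0 counts in a group set at their bound is given where it differs.

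The rule for named genes was also fixed before the data were examined. It took Parp1 and Parp2. For each pairwise comparison it took the 8 genes with the largest fold change in each direction among those past the threshold, with a mean of at least 1 CPM and no overlap between the libraries of both groups. Immunoglobulin segments, predicted gene models and pseudogenes were counted but not named by it. From each list it took up to 4 members past the threshold by smallest p, or the 2 most abundant members as values where a described list had none. Genes named outside the rule, after their values had been seen, are Myc, the members of the overlap between both knockouts, the single genes given per library in the closing section, Tox4, Gm3375 and Gm5828 in the tests of shared reads and the genes of the Ifi200 family and of eosinophils there.

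The alternatives were RLE and upper quartile factors, library size alone, no filter or a stricter filter (1 CPM in at least 3 libraries), DESeq2 1.42.0, limma-voom, the 6 libraries of the compared groups alone, the replicate number as a block, dispersions without the robust step, a threshold of 0.01, a test against a fold of 1.5, removal of immunoglobulin, sex-linked and erythroid genes, and leaving out each library in turn. Added after the data had been seen were an offset for the smooth trend of each library with GC content and transcript length (mgcv 1.9.3), random thinning of all libraries to the smallest total, the level of Xist as a covariate, removal of the genes of all lists of other cells, the lists of the Ifi200 family and of eosinophils, the tests around the targeted genes and a permutation test of the shifts of marker genes between Parp1_KO libraries. The scalings moved the median of all genes by less than 0.1 on the log2 scale. Transcripts of gene models were aligned with blastn 2.17.0. Overlap of calls between both knockouts was set beside simulated groups without change that shared the same WT libraries.

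The procedure was tested on simulated counts for 13122 genes with the means and library sizes of these data. Of genes changed by 1.5-fold, 2-fold and 4-fold, 53.7%, 70.2% and 93.9% were recovered in Parp1_KO against WT and 43.3%, 67.2% and 92.4% in Parp2_KO against WT, with 12 false calls in each. Replicates of each group were compared before averaging and differed by more than sampling noise, so none were merged. The series calls them biological replicates, while the labels do not identify the animal or litter behind each library.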

Results

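RNA was sequenced from pre-B cells of mice that carry the Eµ-Myc transgene, in which the immunoglobulin heavy-chain enhancer drives the Myc oncogene in the B lineage and B cell lymphoma follows. Mice of 3 genotypes were compared, with wild-type PARP genes (WT), without Parp1 (Parp1_KO) or without Parp2 (Parp2_KO), in 3 libraries each. PARP1 and PARP2 are nuclear enzymes that attach ADP-ribose chains to proteins at DNA breaks. The cells came from tumour-free C57BL/6 animals at 4 weeks of age and were taken by flow sorting with a gate for the surface markers of pre-B cells, B220 and CD19 without c-kit, IgM or IgD, after lysis of red cells. The series describes the libraries of a group as biological replicates.

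Total read counts were 37697481, 32668498 and 36447898 in Parp1_KO libraries 1, 2 and 3. They were 23814112, 23976951 and 29004866 in Parp2_KO and 25783979, 23266867 and 24412061 in WT, so each Parp1_KO library was deeper than each of the other 6. After the filter on low counts, 13122 genes were tested. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 12.2 to 23.7.

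The knocked-out genes were examined first. Parp1 (ENSMUSG00000026496, chromosome 1, 180568924 to 180601254, GRCm38) was at 204 ± 6.36 counts scaled to library size (CPM; SD, n = 3) in Parp1_KO, 732 ± 29.8 in WT and 763 ± 37.2 in Parp2_KO. Parp2 (ENSMUSG00000036023, chromosome 14, 50807841 to 50821301) was at 39.3 ± 2.19 CPM in Parp2_KO, 127 ± 3.75 in WT and 126 ± 2.59 in Parp1_KO. Each targeted transcript therefore stood at 27.8% and 31.0% of WT in its own knockout, below every other library. The log2 fold changes were −1.84 (SE 0.061, adjusted p = 3.44e-09) for Parp1 and −1.69 (SE 0.058, adjusted p = 2.95e-09) for Parp2. Counts of whole genes cannot show which exons were removed, and the labels do not name the deleted exons. Myc itself was at 1261 ± 191 CPM in WT, 1157 ± 103 in Parp1_KO and 1114 ± 143 in Parp2_KO and passed in no comparison.

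**Figure D1:**
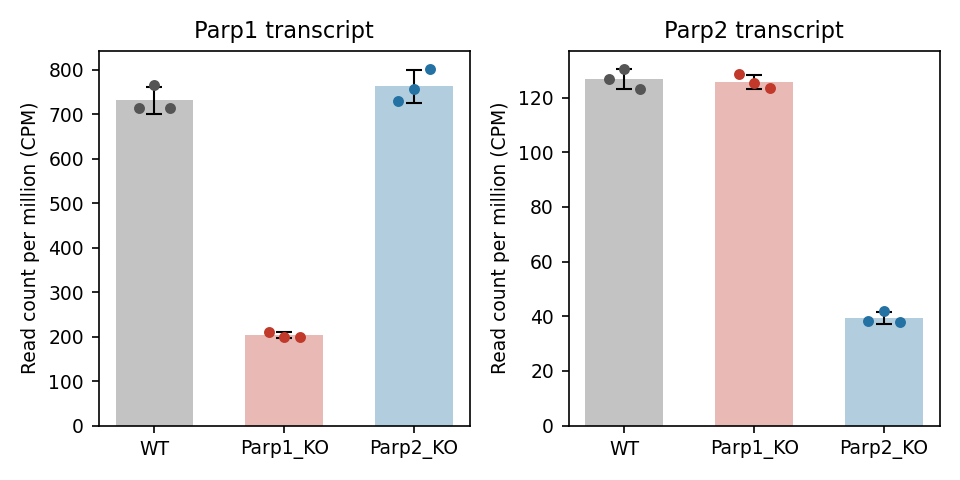
Parp1 and Parp2 transcript levels in CPM (y axes, linear from 0) in the 3 genotypes, with bars at the mean, error bars of 1 SD and a point for each library (n = 3). Parp1 stood at 204 CPM in Parp1_KO against 732 in WT, and Parp2 at 39.3 CPM in Parp2_KO against 127 in WT.

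Along the first principal component of log2 CPM, which held 48.6% of the variance, the Parp1_KO libraries lay between −49.97 and −39.86 and the other 6 between 19.7 and 24.8. Parp2_KO and WT parted along the second component (13.5%), at 6.76 to 24.9 against −27.3 to −3.27, but the Parp1_KO libraries spread over that axis from −22.4 to 14.3. Mitochondrially encoded transcripts took 0.693% to 1.04% of the counts in Parp1_KO and 1.29% to 1.71% in the other 6 libraries.

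**Figure D2:**
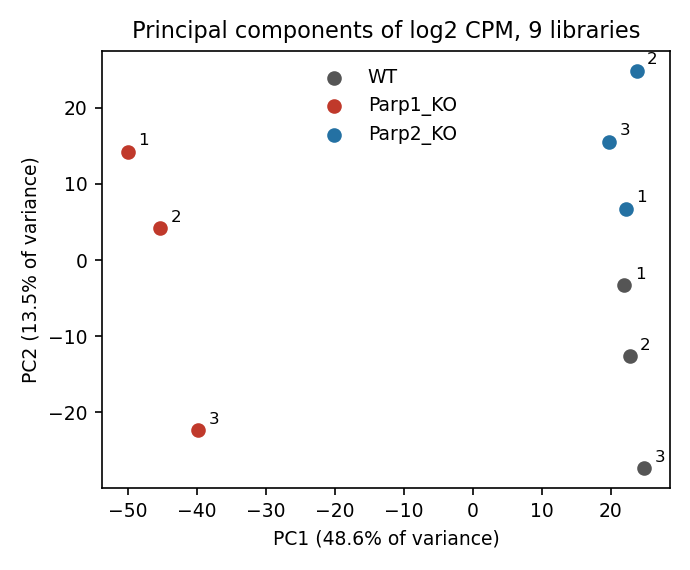
Scores of the 9 libraries on the first 2 principal components of log2 CPM (x axis 48.6% and y axis 13.5% of the variance), coloured by genotype and numbered by replicate. The 3 Parp1_KO libraries lie at −49.97 to −39.86 on the x axis, apart from the 6 others at 19.7 to 24.8.

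The comparison of Parp1_KO with WT addressed which transcripts differ in pre-B cells without PARP1 before a Myc-driven lymphoma is present. Markers of blood cells other than pre-B cells were higher in Parp1_KO, by a median log2 fold change of 4.21 for erythroid and 3.86 for neutrophil genes. camera also called the lists for nuclear oxidative phosphorylation, antigen presentation, the type I interferon response and NF-kB higher, at medians of 0.23 to 0.50, with 26 of 38, 11 of 20, 13 of 38 and 10 of 23 genes higher, and the mitochondrially encoded genes lower, at a median of −1.01. All these list calls were lost with an estimated correlation (adjusted p = 0.107 to 0.675), and the mitochondrial list also lost its call, and its 7 genes theirs, once each library's trend with GC content and length was taken out (median −0.32, adjusted p = 0.23). In all, 1585 genes rose and 1898 fell among 13122 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 585 of them by more than 2-fold.

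Ifi204 and Ifi211, interferon-inducible genes of the Ifi200 family on chromosome 1, were among the 8 largest named rises. Both lie within 10 Mb of Parp1, where calls were more frequent than elsewhere (see the closing section). Ifi204 (173747293 to 173766943) rose from 0.0553 ± 0.0249 to 24.6 ± 1.96 CPM (log2 fold change 8.69, SE 0.35, adjusted p = 2.3e-08). Ifi211 (173896345 to 173913046) had 939 counts in the Parp1_KO libraries and 0 in WT, at least 209-fold higher. Their relatives Ifi213 and Ifi209 were among the 8 largest named falls, at −3.70 (SE 0.46, adjusted p = 0.000139) and −1.71 (SE 0.14, adjusted p = 7.3e-05), with Ifi209 at 86.3 ± 16.5 against 283 ± 24.2 CPM. Members of this family are similar in sequence and lie side by side, so reads assigned among them are uncertain. Other falls were those of Fam20c, a kinase of secreted proteins, at −3.05 (SE 0.57), and the clock-related factor Arntl2 at −2.86 (SE 0.58). The mitochondrial transcripts mt-Tt and mt-Nd6 fell by 2.49 and 2.08 and the small nucleolar RNA Snord72 by 1.69, and these 3 calls ended once each library's trend with GC content and length was taken out (adjusted p = 0.0755, 0.121 and 0.519). The call of mt-Nd6 also ended without Parp1_KO 3 (adjusted p = 0.0507).

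The remaining 6 of the 8 largest named rises were genes of other blood cells. The interleukin receptor chain Il2rb had 493 counts in Parp1_KO and 0 in WT, at least 110-fold higher. The basophil protease Mcpt8 had 1372 counts against 3, a ratio of 306 (95% counting interval 104 to 1490), and the related protease Prss34 rose by 7.86 (SE 0.74, adjusted p = 0.000289). Siglech, a receptor of plasmacytoid dendritic cells, was at 30.4 ± 27.1 against 0.0704 ± 0.0872 CPM, the T cell receptor partner Cd4 had 1039 counts against 2 (ratio 347, 96.0 to 2870), and Cd7 851 against 2 (ratio 285, 78.5 to 2350). limma-voom did not call Siglech, Cd4 or Cd7 (adjusted p = 0.517, 0.287 and 0.170). The Siglech call held without Parp1_KO 3 and ended without any of the other 8 libraries (adjusted p = 0.0525 to 0.108), that of Cd4 ended without WT 1, 2 or 3 (0.079, 0.0594 and 0.0712), and that of Cd7 without WT 1 or WT 3 (0.0502 and 0.0691). The intervals cover counting error only. Over Parp1_KO 1, 2 and 3, Cd4 was at 14.7, 13.6 and 0.463 CPM and Cd7 at 11.1, 11.8 and 0.790. Siglech was at 37.4, 53.3 and 0.490 CPM in the same libraries. Cd4 and Cd7 thus varied with this dendritic cell gene and do not by themselves point to T cells.

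Among lists of marker genes for cells the gate should exclude, all 13 measured erythroid genes rose, including the membrane protein Gypa by 4.50 (SE 0.40), the carbonic anhydrase Car2 by 3.01 (SE 0.22), which stood at 11.4 ± 2.58 against 1.42 ± 0.204 CPM, and the membrane skeleton gene Epb42, with 234 counts against 2 (ratio 78.3, 21.4 to 650). All 15 genes of neutrophils and their precursors rose, among them the granulocyte receptor Csf3r by 4.21 (SE 0.69) and Retnlg by 4.09 (SE 0.54). So did 9 of 13 monocyte and macrophage genes, such as the chemokine receptor Ccr2 by 3.59 (SE 0.64), with a list median of 3.05 that was 1.74 without Parp1_KO 3. The 9 megakaryocyte, basophil and mast cell genes included 7 that rose, at a median of 6.88, or 6.06 with genes at 0 counts in WT set at their bound. Of 9 dendritic cell genes 8 rose (median 4.63) and of 9 T and NK cell genes 6 (median 1.2), and no member of these 6 lists fell. Measured members are those that passed the low-count filter, which a gene could do through the Parp1_KO libraries alone. In the order given, 7, 7, 9, 6, 5 and 6 members were under 1 CPM in WT. Such members could hardly fall, so the absence of falls carries little weight. The T and NK median was 3.41 to 6.04 when any 1 library other than Parp1_KO 2 was left out. Without the low-count filter it was 4.38 and that of the megakaryocyte, basophil and mast cell list 1.01. Adjusted over the list alone, 13, 15, 11, 8, 8 and 6 members rose, in the order given. camera called each list with its preset correlation (adjusted p = 5.66e-12, 2.3e-10, 3.07e-05, 1.65e-06, 0.000574 and 0.00153), and each call was lost with an estimated correlation (adjusted p = 0.107 to 0.525). After the GC and length offset 13, 15, 7, 7, 4 and 4 members were called higher, in the same order, and limma-voom called 13, 6, 3, 7, 1 and 4. Stromal and endothelial genes (2 of 6 higher, Pdgfrb and Cdh5, the second of which was not called without WT 1 or WT 3, at 0.0566 and 0.0591; list adjusted p = 0.0865, and 0.0141 with the offset) and plasma cell genes (4 higher and 1 lower of 8; adjusted p = 0.0991) did not pass as lists. Jchain, the joining chain of secreted antibodies, rose by 1.99 (SE 0.38). The list of immature and mature B cells had 2 of 19 higher (adjusted p = 0.658), one of them Plac8 at 372 ± 23.2 against 273 ± 11.7 CPM.

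**Figure D3:**
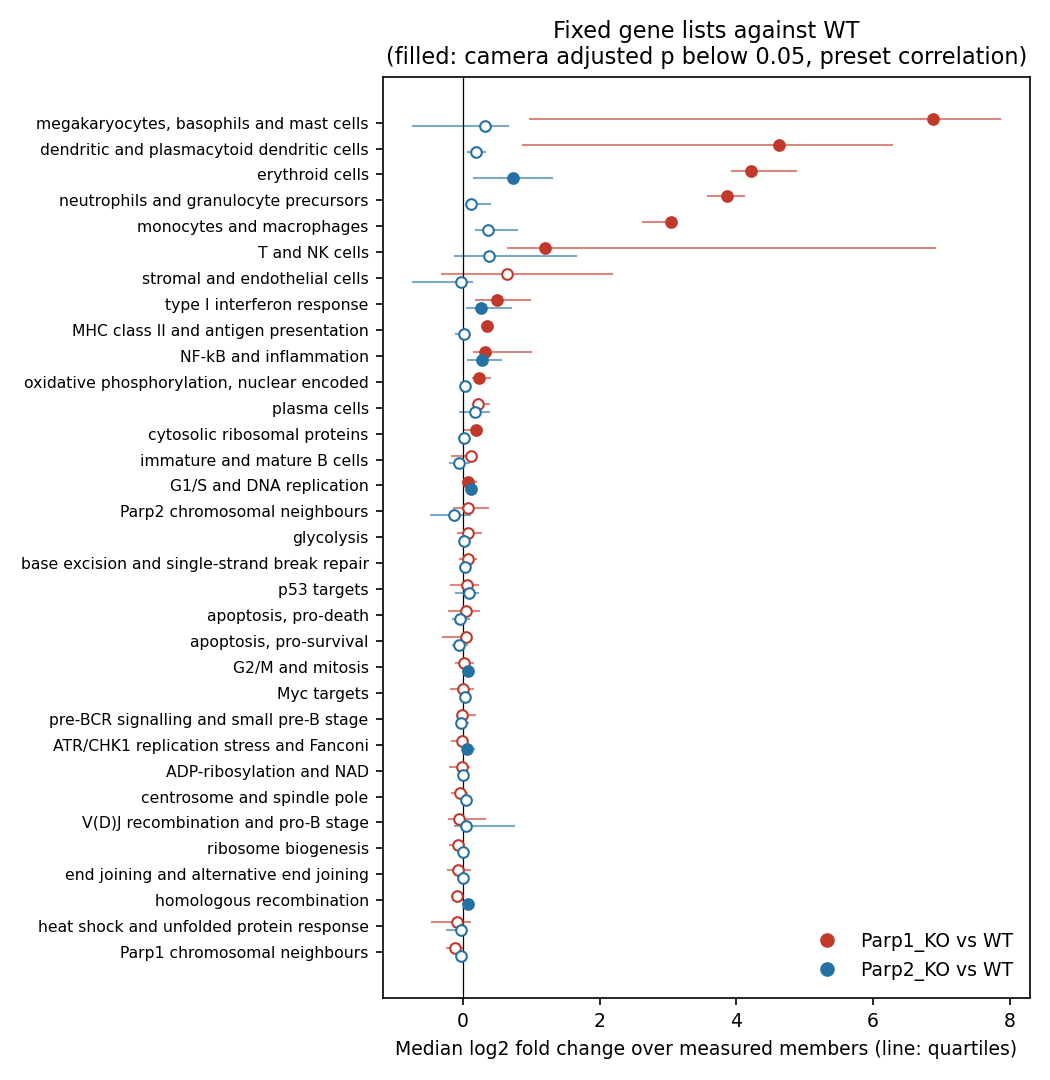
Median log2 fold change against WT over the measured members of each gene list (points; lines span the quartiles) for Parp1_KO and Parp2_KO, without the quality lists. Filled points passed camera with its preset correlation, and none passed with an estimated one. Genes at 0 counts in 1 group enter at their fitted value, and with such genes at their bound the list of megakaryocytes, basophils and mast cells moves from 6.88 to 6.06 in Parp1_KO and from 0.32 to 0 in Parp2_KO, neighbours of Parp2 from 0.07 to −0.0012 in Parp1_KO, and neutrophils from 0.12 to 0.10 in Parp2_KO.

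In the list for nuclear-encoded oxidative phosphorylation 26 of 38 genes rose and 0 fell (median 0.23, camera adjusted p = 2.89e-10, and 0.385 as the adjusted p with an estimated correlation). Its leading members were the cytochrome c oxidase subunits Cox6a1, at 250 ± 6.72 against 156 ± 8.52 CPM (0.68, SE 0.070), Cox5a (0.57, SE 0.067) and Cox5b (0.76, SE 0.098). All 7 measured members of the list of mitochondrially encoded genes, which holds other subunits of the same chain, fell (median −1.01, camera adjusted p = 0.000105, and 0.49 with an estimated correlation as adjusted p). mt-Nd1 went from 2700 ± 216 to 1296 ± 311 CPM. Adjusted over the list alone, 29 nuclear genes rose and 7 mitochondrial genes fell. After the GC and length offset 13 nuclear genes stayed higher and the list kept its call at a median of 0.12, with Cox6a1 at 0.33. The mitochondrial list kept none of its 7 calls, its median moved from −1.01 to −0.32 and its adjusted p to 0.23.

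MHC class II and antigen presentation genes included 11 higher and 0 lower of 20 (median 0.36, camera adjusted p = 7.95e-06, and adjusted p = 0.469 with an estimated correlation). The peptide transporter Tap1 was at 131 ± 11.8 against 96.6 ± 8.51 CPM (0.44, SE 0.080). The type I interferon list held 13 higher and 4 lower genes of 38 (median 0.50, adjusted p = 0.000105, and adjusted p = 0.675 with an estimated correlation), with the antiviral genes Rsad2 at 4.07 (SE 0.33) and Isg20 at 1.33 (SE 0.22) beside Ifi204. The rise of Ifi204 cannot be told apart from an effect of the region around Parp1. For NF-kB and inflammation the count was 10 higher and 1 lower of 23 (median 0.32, adjusted p = 6.66e-05, and adjusted p = 0.385 with an estimated correlation), with the subunit Relb at 13.5 to 16.5 against 7.94 to 8.39 CPM over the libraries (0.82, SE 0.14). The other called NF-kB genes that the rule took were near the floor in WT. Il1b was at 0.424 to 1.36 CPM in Parp1_KO against 0 to 0.042 in WT and Ccl5 at 0.463 to 2.62 against 0 to 0.0387. Tnfaip2 was at 0.847 to 1.90 against 0 to 0.210 CPM. The NF-kB median was 0.58 without WT 3. Adjusted over the list alone, these 3 lists had 16, 19 and 12 genes higher and 0, 4 and 1 lower. All 3 kept their call after the GC and length offset, with 4, 8 and 6 genes higher and medians of 0.15, 0.37 and 0.20, and Tap1 was then at 0.26. Macrophages and dendritic cells, whose markers were higher in the same libraries, also express genes of these lists.

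Cytosolic ribosomal protein genes moved both ways, 20 higher and 4 lower of 48 (median 0.19, camera adjusted p = 0.00303, and adjusted p = 0.675 with an estimated correlation). Rpl7a was at 147 ± 4.81 against 83.8 ± 7.42 CPM (0.82, SE 0.065), Rps2 rose by 0.68 (SE 0.077) and Rps20 by 0.51 (SE 0.059). These genes have many pseudogene copies, so their counts depend on how the authors assigned shared reads. G1/S and DNA replication genes had 11 higher and 4 lower of 45 (median 0.07, or 0.11 with library size as the scaling, adjusted p = 0.0217, and adjusted p = 0.547 with an estimated correlation), with the licensing factor Cdt1 at 163 ± 2.38 against 120 ± 6.04 CPM (0.44, and 0.19 with the offset). Adjusted over the list alone the counts were 21 and 7 for ribosomal proteins and 12 and 4 for G1/S genes. Both calls were lost after the GC and length offset (adjusted p = 0.63 and 0.121), with 5 ribosomal protein genes higher and 6 lower at a median of −0.03 and 4 G1/S genes higher and 2 lower at 0.02. The G1/S call was also lost without Parp1_KO 3 (adjusted p = 0.0849) and without WT 2 (0.153).

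The DNA repair lists did not pass. Members higher and lower were 3 and 7 of 39 for the ATR pathway and Fanconi genes, 1 and 4 of 24 for homologous recombination, 1 and 4 of 23 for end joining and 2 and 2 of 22 for base excision repair (adjusted p = 0.511, 0.15, 0.707 and 0.336). Exo1, a nuclease of break resection, fell by 0.33 (SE 0.073) and Tdp2, which frees DNA ends from topoisomerase 2, by 0.38 (SE 0.071), and both kept their call after the GC and length offset. The checkpoint kinases Atr (122 ± 5.46 against 165 ± 5.43 CPM) and Chek1 (82.9 ± 2.08 against 113 ± 11.1 CPM) and the end-protection factor Rif1 (206 ± 2.05 against 283 ± 7.86 CPM) also fell. Those 3 calls ended under the offset, where the values of Atr and Rif1 turned to 0.03 and 0.08 and that of Chek1 was −0.21 (adjusted p = 0.103). In the list for ADP-ribosylation and NAD metabolism, Parp1 and 5 other genes fell and 1 rose of 33 (adjusted p = 0.511), with the deacetylase Sirt1 at −0.73 (SE 0.082; −0.48 with the offset).

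Lists of the Myc programme and of stress were likewise not called. Myc targets had 3 higher and 7 lower of 35 (adjusted p = 0.757) with the translation factor Eif4e at −0.40 (SE 0.061), ribosome biogenesis 2 and 10 of 32 (0.093) with the polymerase I factor Rrn3 at −0.38 (SE 0.062), and G2/M genes 4 and 4 of 36 (0.711). The offset instead called both Myc targets and ribosome biogenesis lower (adjusted p = 0.0241 and 0.0101). p53 targets had 2 higher and 4 lower of 32 (0.762), with Trp53inp1 at 248 ± 12.3 against 426 ± 28.5 CPM (−0.78, SE 0.076) and Rrm2b at −0.54 (SE 0.086), which were −0.32 and −0.31 with the offset. Pro-survival genes had 0 higher and 4 lower of 11, among them the caspase inhibitor Xiap at −0.79 (SE 0.079; −0.33 with the offset), but the list median was 0.04 and its mean −0.14 (adjusted p = 0.511). Pro-death genes had 3 higher and 4 lower of 21 (0.774), glycolysis 5 and 1 of 20 (0.436), heat shock and unfolded protein response 0 and 1 of 25 (0.707), immediate early genes 1 and 0 of 26 (0.825) and centrosome genes 2 and 4 of 28 (0.707). Histone genes had 0 of 20 past the edgeR test (2 at an unadjusted p under 0.05; DESeq2 0 and limma-voom 0) and sex-linked genes 0 of 5 (0 unadjusted; DESeq2 0 and limma-voom 0), with adjusted p = 0.957 and 0.72 for the lists. Neighbours of Parp1 on the chromosome had 3 higher and 5 lower of 20 (0.189), with Psen2 at −0.97 (SE 0.090), and neighbours of Parp2 5 and 2 of 20 (0.422). With the GC and length offset the balance of calls turned for glycolysis (1 higher and 6 lower, median from 0.07 to −0.07), neighbours of Parp2 (2 higher and 3 lower, median −0.03) and immediate early genes (0 higher and 1 lower). The median of all tested genes was itself −0.07 under the offset. The medians of glycolysis and of the neighbours of Parp2 therefore show no fall relative to other genes. In the lists that camera did not call in this comparison, counts adjusted over the list alone differed from those over all genes by at most 2 in each direction. Median and mean differed in sign for Myc targets (0.0037 and −0.046), pro-death genes (0.05 and −0.0033) and histones (0.04 and −0.05), and the test ran against the median for p53 targets (median 0.06) and immediate early genes (median −0.07).

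Within the B lineage, V(D)J recombination and pro-B genes had 4 higher and 5 lower of 23 (adjusted p = 0.71) and pre-B cell receptor signalling genes 2 higher and 3 lower of 25 (0.762). Their medians were −0.06 and −0.02 against means of 0.24 and 0.02. The recombinase gene Rag1 (chromosome 2, 101638282 to 101649501) was at 226 ± 21.4 against 384 ± 58.5 CPM (−0.76, SE 0.12, adjusted p = 0.00163), a call that ended under the GC and length offset (−0.54, adjusted p = 0.0544). The cell-cycle inhibitor Cdkn1b was at 86.1 ± 2.13 against 137 ± 12.1 CPM (−0.67, SE 0.064) and the transcription factor Sox4 at −0.35 (SE 0.080), and both kept their call.

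Fold changes in this comparison followed the GC content of the genes (Spearman's rho 0.517 across 13098 genes, which are not independent replicates; −0.0261 for Parp2_KO against WT). The median ran from −0.44 to 0.21 over 10 bins of genes from the lowest to the highest GC content. Taking out each library's trend with GC content and length, a step chosen after the data had been seen, left 1923 genes changed, of which 1297 were original calls with the same sign. It also put the median of all tested genes at −0.0716, and at −0.059 in Parp1_KO against Parp2_KO. List medians under the offset are to be read beside these values. The share of calls that were higher was 45.5% with the main scaling, 56.7% with library size alone, 56.6% with upper quartile factors and 35.1% with the offset, so the balance of rises and falls was not settled by these data.

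**Figure D4:**
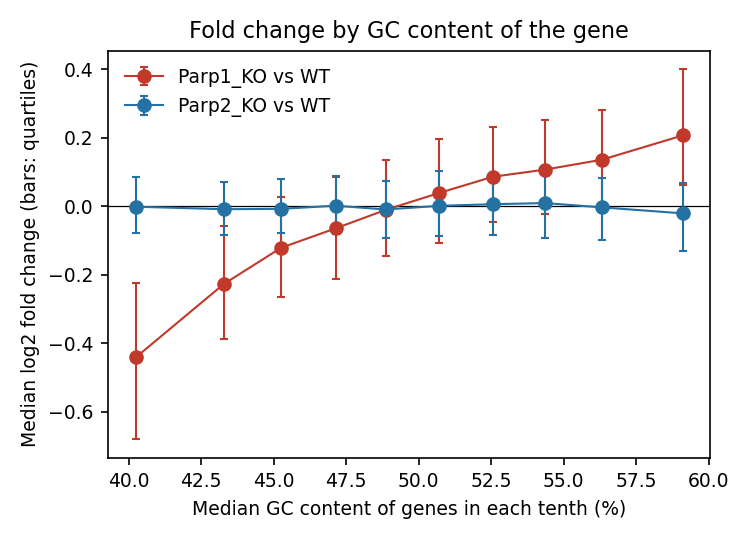
Median log2 fold change (y axis; bars span the quartiles) in 10 bins of the tested genes by GC content (x axis, median GC of each bin in percent). Parp1_KO against WT runs from −0.44 to 0.21, while Parp2_KO against WT stays between −0.0206 and 0.00945.

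The comparison of Parp2_KO with WT asked the same of PARP2, and 14 genes rose and 30 fell, 23 by more than 2-fold (1161 genes at an unadjusted p under 0.05). Ccnb1ip1 (ENSMUSG00000071470, chromosome 14, 50789248 to 50807732), a ubiquitin ligase of the cyclin B1 pathway that lies next to Parp2, had 1985 counts in Parp2_KO and 0 in WT, at least 633-fold higher, at 23.6 to 27.9 CPM in the 3 Parp2_KO libraries. The carbonic anhydrase Car2 rose from 1.42 ± 0.204 to 5.46 ± 0.895 CPM (1.94, SE 0.22, adjusted p = 0.000787), the RNA-binding protein Khdrbs3 by 1.85 (SE 0.25) and the ephrin receptor Epha2 from 22.9 ± 1.81 to 48.2 ± 6.61 CPM (1.08, SE 0.13). Supt16, part of the histone chaperone FACT, rose from 541 ± 53.1 to 798 ± 40.7 CPM (0.56, SE 0.072). The matrix metalloproteinase Mmp14 (chromosome 14, 54431612 to 54445364) fell from 6.33 ± 2.77 to 0.232 ± 0.0771 CPM (−4.72, SE 0.44, adjusted p = 0.000334). Rnase12 fell by 3.65 (SE 0.43), the phosphatase subunit Ppp1r3e by 3.14 (SE 0.22) and the transcription factor Trerf1 by 1.37 (SE 0.19). All of these kept their call without any 1 library and after the GC and length offset.

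Other genes named by the rule were called with all 9 libraries but not without some of them. These were the exchange factor Vav3 (1.57, SE 0.23), Relb (0.84, SE 0.14) and the plasma cell surface protein Sdc1 (0.59, SE 0.095) among the rises and Foxf2 (−3.15, SE 0.48), Rflna (−1.54, SE 0.24) and the amino acid transporter Slc7a7 (−1.39, SE 0.21) among the falls. Rag1 was at 205 ± 22.5 against 384 ± 58.5 CPM (−0.91, SE 0.12, adjusted p = 0.0128) and Lef1, a transcription factor of early B cells, at 68.2 ± 1.66 against 47.3 ± 5.20 CPM (0.53, SE 0.092), while Haus4 of the spindle fell by 0.41 (SE 0.059). Without Parp2_KO 1 the adjusted p was 0.0513 for Vav3, 0.135 for Relb, 0.121 for Sdc1, 0.142 for Foxf2, 0.0927 for Rflna, 0.162 for Lef1 and 0.064 for Haus4. Without Parp2_KO 2 it was 0.0685 for Vav3, 0.129 for Foxf2, 0.0578 for Rflna, 0.084 for Slc7a7, 0.147 for Lef1 and 0.0526 for Haus4. Without Parp2_KO 3 it was 0.0545 for Relb, 0.0714 for Sdc1, 0.0816 for Foxf2, 0.0513 for Slc7a7, 0.0803 for Rag1 and 0.0799 for Lef1. Without WT 1 it was 0.0635 for Vav3, 0.148 for Relb, 0.102 for Sdc1, 0.0681 for Rflna, 0.0527 for Rag1 and 0.169 for Lef1. Without WT 2 it was 0.0771 for Relb, 0.0687 for Sdc1 and 0.104 for Lef1, and without WT 3 it was 0.0675 for Relb and 0.0675 for Rag1. Rag1 also missed the threshold after the GC and length offset (−0.89, adjusted p = 0.0731) and without the low-count filter (0.0612). limma-voom did not call Relb (0.0737) or Foxf2 (0.135). The number of called genes itself ran from 23 without Parp2_KO 1 to 77 without Parp1_KO 1, with 26 and 28 without Parp2_KO 2 or 3 and 25 without WT 1, and was 226 with DESeq2.

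The calls clustered around the deleted gene. Within 10 Mb of Parp2, 18 of 146 tested genes were called with Parp2 itself among them (3 higher and 15 lower), 12.3% against 0.201% of the other genes (Fisher's exact test, two-sided, p = 1.93e-24). Leaving out Parp2, 17 of 145 were called (3 higher and 14 lower, Fisher's exact p = 7.11e-23). Of the genes named above, Ccnb1ip1, Supt16, Mmp14, Rnase12, Ppp1r3e, Slc7a7 and Haus4 were among these calls. Their changes cannot be told apart from an effect of the chromosomal region. Of the 20 measured neighbours fixed as a list, 3 rose and 3 fell (5 and 8 adjusted over the list alone; median −0.13 and mean 0.41; camera adjusted p = 0.337), with the telomerase-associated Tep1 at 59.7 ± 2.80 against 97.3 ± 1.89 CPM (−0.70, SE 0.057).

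**Figure D5:**
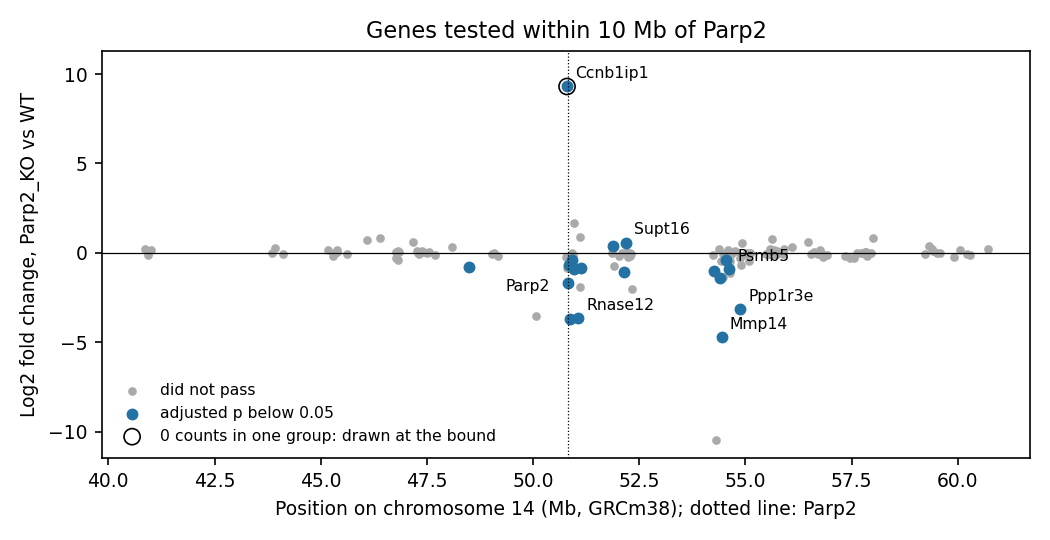
Log2 fold change between Parp2_KO and WT (y axis) for tested genes within 10 Mb of Parp2, by position on chromosome 14 in Mb (x axis; dotted line, Parp2), with the 18 called genes, Parp2 included, in blue. The circled point is Ccnb1ip1, drawn at its bound of 9.31 because WT had 0 counts, and Mmp14 (−4.72) lies nearly 4 Mb from Parp2. The grey point near the lower edge did not pass the test.

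Among gene lists, camera with its preset correlation called 7 higher and 0 lower. They were G1/S and DNA replication (median 0.11, adjusted p = 5.14e-11), type I interferon (0.26, 0.000217), G2/M (0.08, 0.00025), NF-kB (0.28, 0.00025), ATR pathway and Fanconi genes (0.05, 0.000992), homologous recombination (0.07, 0.00281) and erythroid genes (0.73, 0.00488). Each call was lost with an estimated correlation (adjusted p = 0.295, 0.908, 0.85, 0.745, 0.392, 0.745 and 0.85 in that order). Single members passed in 2 of them, Relb in the NF-kB list and Car2 in the erythroid list. In the other 5, edgeR called 0 members, with 16 of 45, 5 of 38, 3 of 36, 9 of 39 and 4 of 24 at an unadjusted p under 0.05, while DESeq2 called 4, 1, 0, 3 and 0 and limma-voom 0 in each. Adjusted over the list alone, 3 G1/S, 3 NF-kB and 3 ATR pathway genes and 1 erythroid gene rose. The abundant replication genes Rrm1 and Mcm6 were at 750 ± 37.6 against 698.5 ± 23.3 and 858 ± 36.4 against 813 ± 30.5 CPM, differences that did not pass. The erythroid call ended without Parp2_KO 1 (adjusted p = 0.0598), Parp2_KO 3 (0.124) or WT 2 (0.191), that of G2/M without Parp2_KO 2 (0.0897), and that of homologous recombination without Parp2_KO 2 (0.211) or WT 2 (0.0543). Leaving out 1 library also moved the interferon median to 0.45 (Parp2_KO 1), 0.13 (Parp2_KO 3), 0.17 (WT 1) or 0.39 (WT 3), and Xist as a covariate moved it to 0.16. The erythroid median became 1.35 (Parp2_KO 2), 0.47 (Parp2_KO 3) or 0.35 (WT 2), that of G2/M 0.05 (Parp2_KO 2) or 0.04 (WT 3), that of NF-kB 0.13 (Parp2_KO 3) and that of homologous recombination 0.05 (Parp2_KO 2), while the offset took the ATR pathway median to 0.04. The number of called lists rose to 11 without Parp2_KO 2 and to 11 without WT 3.

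In the lists not yet described the count of called members was at most 2. Parp2 was the member called in the ADP-ribosylation list, Sdc1 in the plasma cell list, Haus4 in the centrosome list, and Lef1 (higher) and Rag1 (lower) among V(D)J recombination genes (camera adjusted p = 0.724, 0.0986, 0.222 and 0.537). V(D)J genes that rose numbered 4 and those that fell 2 when adjusted over the list alone. edgeR called 0 of 20 MHC class II genes, with 4 at an unadjusted p under 0.05 and 0 calls by DESeq2 or limma-voom. For the 38 nuclear oxidative phosphorylation genes the same figures were 0, 1 and 0, and for the 15 neutrophil genes 0, 1 and 0. S100a9 of neutrophils was at 5.78 to 7.90 CPM against 6.51 to 8.71 CPM in WT and Cd74 of the MHC class II pathway at 933 ± 82.5 against 914 ± 112 CPM, neither of which passed.

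Both knockouts were then compared directly, which tests whether their changes against WT differ. Relative to Parp2_KO, 1471 genes were higher and 1709 lower in Parp1_KO, 566 by more than 2-fold (1989 genes in all without Parp2_KO 2). Ifi211 was at least 219-fold higher (939 counts against 0), Ifi204 higher by 7.99 (SE 0.33), Prss34 by 8.73 (SE 0.81) and Mcpt8 by 7.79 (SE 0.78), and the adhesion protein Cdh1 had 497 counts against 3 (ratio 116, 39.4 to 564). Ccnb1ip1 had 1 count in Parp1_KO and 1985 in Parp2_KO (ratio 2840, 509 to 112000). Ifi213 was lower at −4.42 (SE 0.45), Ifi206 at −2.23 (SE 0.35), Ifi208 at −2.03 (SE 0.35) and Fam20c at −2.67 (SE 0.58). Lef1 was at 45.4 ± 4.99 against 68.2 ± 1.66 CPM (−0.59, SE 0.091). Of the other genes the rule named, Siglech, Runx2, Cd7, Arntl2, mt-Tt and mt-Nd6 were called in the main fit and lost under at least 1 alternative. limma-voom gave an adjusted p of 0.524, 0.406 and 0.216 for Siglech, Runx2 and Cd7, the GC and length offset 0.0523, 0.0901 and 0.078 for Siglech, mt-Tt and mt-Nd6, and the fit without Parp2_KO 1 gave 0.107, 0.0896 and 0.0726 for Siglech, Runx2 and Arntl2. Without Parp1_KO 1 these 3 were at 0.0661, 0.0532 and 0.063. Siglech and Runx2 also missed the threshold without Parp2_KO 2 (0.111 and 0.0874) or Parp2_KO 3 (0.0962 and 0.0824), and Siglech without Parp1_KO 2 (0.0651), WT 1 (0.0553), WT 2 (0.054) or WT 3 (0.0533).

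The same marker lists of other cells stood apart as against WT. Higher in Parp1_KO than in Parp2_KO were 13 of 13 erythroid genes (median 3.93), 15 of 15 neutrophil (3.66), 7 of 9 megakaryocyte, basophil and mast cell (6.11, or 6.02 with bounds), 7 of 13 monocyte (2.31), 6 of 9 T and NK (2.19) and 6 of 9 dendritic cell genes (3.90). The monocyte median was 1.10 without Parp1_KO 3, and the T and NK median 3.34 to 5.94 when any 1 library other than Parp1_KO 2 was left out. Without the low-count filter the T and NK median was 4.27 and that of the megakaryocyte list 2.38. camera called each (adjusted p = 1.18e-10, 8.33e-10, 8.67e-07, 0.000216, 0.000865 and 0.00347), and each was lost with an estimated correlation (adjusted p = 0.18 to 0.632). Adjusted over the list alone 13, 15, 7, 10, 6 and 8 members were higher, in the order given, while limma-voom called 13, 4, 7, 4, 3 and 0. With the GC and length offset 13, 14, 7, 6, 4 and 2 were called higher. For dendritic cell genes, 8 of the 9 were at an unadjusted p under 0.05, and DESeq2, which applied its own filter to the full list, called 11. Nuclear oxidative phosphorylation genes had 20 of 38 higher (median 0.20, adjusted p = 3.52e-08), with Uqcrb of complex III at 35.1 ± 2.36 against 22.1 ± 1.36 CPM, and all 7 measured members of the mitochondrially encoded list were lower (median −1.10, adjusted p = 3.53e-05). Both calls were lost with an estimated correlation (adjusted p = 0.398 for each), and adjusted over the list alone 24 nuclear genes were higher and 7 mitochondrial genes lower. With the GC and length offset 10 nuclear genes were higher (median 0.08, adjusted p = 5.55e-06) and 1 mitochondrial gene was lower (median −0.37, adjusted p = 0.0421).

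MHC class II and antigen presentation genes had 13 of 20 higher (median 0.32, adjusted p = 6.08e-06, and adjusted p = 0.398 with an estimated correlation), and 3 of 20 with the GC and length offset (median 0.12, adjusted p = 0.000208). H2-Eb1 was at 306 ± 11.8 against 190 ± 20.8 CPM (0.69, SE 0.082), H2-Aa higher by 0.53 (SE 0.069) and H2-Ab1 by 0.61 (SE 0.090; 0.37 with the GC and length offset). Ribosomal protein genes had 17 higher and 4 lower of 48 (median 0.15, adjusted p = 0.00446, and adjusted p = 0.694 with an estimated correlation), a call lost under the GC and length offset (8 higher and 4 lower, median −0.02, adjusted p = 0.427). Lists called lower in Parp1_KO than in Parp2_KO were homologous recombination (8 of 24 lower, 0 higher, median −0.17, adjusted p = 0.000865), the ATR pathway and Fanconi genes (11 lower and 2 higher of 39, −0.11, 0.00559) and ribosome biogenesis (10 lower and 2 higher of 32, −0.09, 0.034). All 3 were lost with an estimated correlation (adjusted p = 0.398, 0.393 and 0.684). The offset left 2 homologous recombination genes lower (adjusted p = 0.0235) and 7 ATR pathway genes lower and 1 higher (adjusted p = 0.0421), and library size as the scaling moved the ATR pathway median to −0.07. When adjusted over the list alone, 14 MHC class II genes were higher, 23 ribosomal protein genes were higher and 5 lower, and 9, 14 and 11 genes of the 3 lower lists were lower. The GC and length offset also called Myc targets (adjusted p = 0.00586) and G1/S genes (0.0409) lower and type I interferon (0.00215) and stromal genes (0.00841) higher, which the main fit did not. Exo1 was lower at −0.39 (SE 0.073), the helicase Blm at −0.37 (SE 0.071) and Bard1, the partner of BRCA1, at −0.35 (SE 0.078), and with the GC and length offset Blm was at −0.24 and Bard1 at −0.22. The ribosome biogenesis call ended with library size as the scaling (adjusted p = 0.102) and without Parp1_KO 1, Parp1_KO 2 or Parp2_KO 3 (0.0784, 0.0854 and 0.134). The share of higher genes was 46.3%, and 57.4% with library size alone.

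Both knockouts shared 20 called genes, 14 with the same sign (8 higher, 6 lower) and 6 with opposite signs. Car2 rose in both, by 3.01 and 1.94, Vav3 by 0.97 and 1.57, Epha2 by 1.05 and 1.08, Relb by 0.82 and 0.84, and Khdrbs3 by 0.86 and 1.85. Car2 belongs to the erythroid list, whose 13 measured genes all rose in Parp1_KO, while in Parp2_KO it was the 1 member called. Rag1 fell in both, by 0.76 and 0.91, and Trerf1 by 0.52 and 1.37. The 6 genes of opposite sign (Osgep, Gm49342, Rnase6, Abhd4, Haus4 and Psmb5) were higher in Parp1_KO and lower in Parp2_KO and lie near Parp2 on chromosome 14. Independent lists of these sizes would share 1.69 higher and 4.34 lower genes, and 20 simulations of unchanged groups against the same WT libraries gave 0.15 shared calls on average and at most 2. The simulated lists held 0 to 4 calls each, so this value says nothing of the overlap of lists as long as the observed ones. The correlation of fold changes across genes was 0.306 (0.51 in the simulations) and their covariance 0.0841 (0.0413). The 3 WT libraries cannot be split into parts of at least 2, so part of this excess may come from the shared controls. Among these genes, Haus4, Osgep and Rag1 were not called in Parp1_KO under the GC and length offset (0.483, 0.186 and 0.0544), and Osgep not without Parp1_KO 1 or WT 1 (0.0667 and 0.0694). Vav3, Relb, Rag1, Haus4 and Osgep were each also lost in Parp2_KO without at least 1 library. The 14 shared calls were 75 with DESeq2 and 6, 6, 4 and 9 without Parp2_KO 1, Parp2_KO 3, WT 1 or WT 2.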

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

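Of the tests reported in this part, those of GC content, depth and batch as sources of the broad shift, of a lower share of pre-B cells, of cells of other types, of strain DNA, of a local effect and of the reads of Psmb5 and Tox4 were chosen after the result was seen.

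The change against WT differed between Parp1_KO and Parp2_KO for 3180 genes and 13 gene lists, by the direct test of the difference. Fold changes of the called genes covered both directions, with 1471 higher and 1709 lower in Parp1_KO. The list calls rest on the preset correlation, and 0 lists passed with an estimated one (4 at an unadjusted p under 0.05).

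For each pairwise comparison the 6 libraries can be split in 10 ways, too few for a share under 0.05. The real split called 3483, 44 and 3180 genes for Parp1_KO against WT, Parp2_KO against WT and Parp1_KO against Parp2_KO, and in each case 1 split, the real one, reached that count while the highest other called 0. For a difference between any genotypes 100 of the 280 splits of the 9 libraries were drawn. The real one called 3385 genes and was the only 1 of the 100 to reach that count, a share under 0.05. This argues against a random division of the libraries as the source of the count. The highest other split called 3327, so the count hardly sets the 3 genotypes apart from every other grouping. The 4 other splits that kept the Parp1_KO libraries together called 2445 to 3327 genes and the rest at most 16, which points to the distance of those 3 libraries from the other 6 as the structure behind the count.

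The first pattern is the broad shift in Parp1_KO. After every library had been thinned to 23266867 counts 3363 genes were called, so the calls did not rest on the extra reads of the Parp1_KO libraries. Thinning cannot show whether depth marks another library preparation. A trend with GC content and length as the whole cause is argued against, since 1297 of 3483 calls kept their sign and passed with that trend taken out. This was likely beforehand, as 585 calls exceeded 2-fold while medians over the GC bins ran from −0.441 to 0.207. The count of kept calls says little of the smaller changes, and 610 genes were called only with the offset. The trend is a candidate source of part of the calls: fold changes followed GC content with a rho of 0.517 across genes, and 62.3% of the calls ended with the offset (16 others kept a call with the opposite sign), their median absolute fold change moving from 0.337 to 0.135 with a median SE of 0.0784 and 0.0786. A library batch that coincides with genotype cannot be told apart from the loss of Parp1, because all 3 Parp1_KO libraries were deeper than every other library and no batch is labelled. An effect of the genotype stays open as well.

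The second pattern is the set of transcripts of other blood cells in Parp1_KO. Hbb-bs of red cells was at 480, 258 and 223 CPM in Parp1_KO 1, 2 and 3 against 9.27 to 35.5 in the other 6 libraries, and S100a8 of neutrophils at 75.6, 12.9 and 47.4 against 2.65 to 4.24. A GC trend is argued against by its size, with medians of −0.441 to 0.207 over the GC bins of all genes. The medians of the 5 lists that hold these genes ran from 3.05 (monocytes) to 6.88 (megakaryocytes, basophils and mast cells, 6.06 with bounds). That 46 of 52 such genes stayed higher with the offset was therefore likely beforehand and adds little. Cells of other types that passed the gate and red cell lysis are a candidate source. Shifts of the called markers between Parp1_KO libraries differed by cell type list in all 3 pairs of libraries (permutation test across 5 lists, adjusted p at most 0.00049). That test treats genes as independent and does not ask whether each list moves as one. Neutrophil genes did between libraries 1 and 2 (quartiles 1.79 to 2.54), but monocyte genes moved both ways between libraries 1 and 3 (−2.22 to 1.41) and 2 and 3 (−2.31 to 0.828). A lower share of pre-B cells that raised every other type alike is argued against, since the 52 called members of 5 lists shifted by different amounts between Parp1_KO libraries (the same test, adjusted p = 1.5e-05 for libraries 1 and 2 from a permutation p of 1e-05, the smallest these permutations can give). The test cannot address a lower share of pre-B cells with a mix of other cells that varied between libraries, which would give such shifts too. From library 2 to library 1 neutrophil genes stood higher by a median log2 of 2.30 and erythroid genes by 0.551, with dendritic cell genes at −0.198. The mix of these transcripts therefore differed between libraries of the same genotype. Whether that arose in the Parp1_KO marrow or in each sort was not tested and stays open.

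The third pattern is the cluster of Parp2_KO calls around Parp2. A local effect of the knockout allele within 1 Mb as the whole cause is argued against by 10 calls at 1 to 10 Mb, beside 7 within 1 Mb other than Parp2 itself, while DNA of another strain carried with the allele is a candidate source (Fisher's exact test of those 10 calls against the rest of the genome, p = 1.35e-12). Reads of Ccnb1ip1 counted on the processed pseudogenes Gm3375 (chromosome 7, 3181093 to 3181888) or Gm5828 (chromosome 1, 16768279 to 16770138), which rose with it, are argued against by 0 and 0 alignments of their transcripts. These pseudogenes are near-identical to Psmb5 and Tox4 instead. Psmb5 (54614119 to 54618022) and Tox4 (52279146 to 52296401) both lie on chromosome 14 within 10 Mb of Parp2. Reads of Tox4 counted on Gm5828 (96.66% identity over 1858 bases) cannot be told apart from separate changes: Tox4 was lower than in WT by 3.87 ± 0.94 (SE) CPM for each CPM gained, but its 85.19 CPM were no lower than the 83.83 CPM of Parp1_KO, where Gm5828 stayed at 0.0373 CPM. For Psmb5 and Gm3375 (98.87% over 796 bases) the ratio of 0.479 ± 0.045 lay under the stated bound of 0.5 by less than its SE and was 0.703 ± 0.025 against Parp1_KO, so sharing of reads between them cannot be told apart from separate changes.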

How the results depend on the processing

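The GC and length offset, thinning, the Xist covariate and the removal of all genes of other cells were chosen after the data had been seen, and the cause of the differences given here was not tested except where fewer libraries or a stricter criterion make it plain. In Parp1_KO against WT 3483 genes became 287 with a fold above 1.5, 1923 with the GC and length offset, 1825 at a threshold of 0.01 and 2331 to 3590 without single libraries. In Parp2_KO against WT 44 became 157 without a low-count filter, 226 with DESeq2, 12 with a fold above 1.5, 77 from the 6 libraries of both groups only, 23 at 0.01 and 23 to 77 without single libraries. In Parp1_KO against Parp2_KO 3180 became 260 with a fold above 1.5, 1624 with the offset, 1666 at 0.01 and 1989 to 3399 without single libraries, and for any genotype 3385 became 1813 with the offset, 1794 at 0.01 and 2496 to 3483. Gene lists past the threshold fell from 13, 7 and 13 to 0, 0 and 0 with an estimated correlation, and fry called 1 for Parp2_KO against WT. Without single libraries they were 12 to 14, 5 to 11 and 12 to 16. Calls shared by both knockouts with the same sign were 14, and 75 with DESeq2, 4 at 0.01 and 4 to 21 without single libraries. Without the genes of all lists of other cells the counts were 3434, 43, 3139 and 3344.

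Under the offset the fold changes of Atr (0.03168 and 0.02952), Rif1 (0.07711 and 0.08698) and Apex1 (−0.002638 and −0.0045) turned sign against WT and Parp2_KO, and Mzb1 (−0.02558) against WT. Of 367 named results it left 243 with the same direction and call, 117 without the call and 7 reversed, while DESeq2 left 362 of 364, limma-voom 345 of 367 and any 1 library less 330 to 348 of 367. In Parp2_KO the heat shock list, not called at a median of −0.02, ran from −0.13 to 0.1231 without single libraries and was called higher without WT 3 (0.1231). The immediate early list, also not called, had a median of 0.09 against a downward direction in camera and ran from −0.6254 to 0.6584. camera called it higher without Parp2_KO 2 (0.4292) and lower without Parp2_KO 3 (−0.6254).

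With the replicate number as a block (replicate block), 81 genes were called in Parp2_KO against WT and 27 shared calls were found, while 111 of 111 list results and 364 of 367 named results stayed the same (Foxf2 in Parp2_KO missed the threshold at an adjusted p of 0.063 and Jund in Parp1_KO at 0.0601 and 0.0564). The numbers did not pair the libraries: deviations of same-numbered libraries correlated by −0.135 to 0.326, and 4 of 6, 2 of 6 and 0 of 6 libraries correlated best with their own number. Depth limits the genes near the floor, and of 1.5-fold changes in simulated data 43.3% were recovered in Parp2_KO against WT.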

Other observations

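Neither list described in this part was fixed before the data were examined, and both were chosen after Ifi204, Ifi211 and the basophil genes had been seen. The Ifi200 family, interferon-inducible sensors and regulators encoded side by side at 173 Mb on chromosome 1 within 10 Mb of Parp1, split in Parp1_KO. Of 11 measured members 5 were higher than in WT and 6 lower. Ifi214 was at 18.7 ± 4.86 against 2.77 CPM and the DNA sensor Aim2 at 58.7 against 39.7, beside Ifi204, Ifi211 and Ifi207. Mndal was at 116 against 181 CPM and Ifi203 lower by −0.39, beside Ifi213, Ifi209, Ifi206 and Ifi208. With the GC and length offset 5 were called higher and 4 lower. In Parp2_KO against WT edgeR called 0 of the 11 (3 at an unadjusted p under 0.05; DESeq2 0 and limma-voom 0). Reads shared between these similar genes leave the level of each uncertain.

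Eosinophil genes were also higher in Parp1_KO, 6 of 8 measured, at a median of 5.51, or 4.77 with genes at 0 counts in WT at their bound. The granule protein Prg2 was at 8.55, 9.08 and 6.59 CPM in Parp1_KO 1, 2 and 3 against a mean of 0.299 in WT, and the peroxidase Epx at 1.2 to 2.39 CPM against 0 in the other 6 libraries. In Parp2_KO edgeR called 0 of the 8 (0 at an unadjusted p under 0.05; DESeq2 0 and limma-voom 0). Markers of other cells varied between the Parp1_KO libraries, with Siglech at 37.4, 53.3 and 0.490 CPM and the basophil protease Mcpt8 at 6.37, 10.2 and 21.5 CPM.

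Around Parp1, 65 of 148 tested genes within 10 Mb, Parp1 itself included, were called in Parp1_KO against WT, 43.9% against 26.4% elsewhere (Fisher's exact test, two-sided, p = 5.25e-06). Changes of more than 2-fold made up 22.3% against 4.23% (p = 7.73e-15, exact test). The Ifi200 genes lie in this window. Whether DNA of another strain was carried with the Parp1 knockout allele was not tested. The expression of sex-linked genes divided the libraries within each genotype, with Xist high in Parp1_KO 1 and 2, Parp2_KO 2 and 3 and WT 1, while the labels used here give no sex.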
